A study of Homo sapiens with 8 samples.

How the data were processed

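PC3 is an established line derived from human prostate carcinoma. Per the labels, PC3 cells in DMEM with glutamine and foetal bovine serum were transfected with either a non-specific control siRNA or an siRNA against TRPM2-AS, a transcript antisense to the calcium channel gene TRPM2, and RNA was taken 48 hours later. Total RNA was purified on RNeasy columns, checked on a Bioanalyser, labelled with biotin and hybridised to Illumina bead arrays in 1 colour. The labels give 8 samples, 4 of each siRNA, and do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

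The first deposited table holds the non-normalized intensity of each probe in 8 columns and, per the file headers, a detection p-value beside each signal. The authors exported it from BeadStudio, per the submitters' processing notes, and its version and background setting are not given in the sources used here. From the values, the signals were not background subtracted and the detection p-values move in steps of 1 in 759. The second deposited table holds the authors' processed intensity of each sample on a linear scale. All of its columns share 1 distribution, so from the values the authors' step was quantile normalization without background subtraction; the submitters' processing notes name limma with no version.

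The columns of the first table are named by group and number and were set against the processed values of the samples. Of the 8 columns, 7 ranked the 48798 shared probes exactly as 1 sample of their own named group did (Spearman rho of 1). Column and replicate numbers differ: control columns 2 and 3 are control replicates 3 and 2, and TRPM2-AS siRNA columns 1, 3 and 4 are replicates 1, 2 and 4. The remaining column, named as the TRPM2-AS siRNA column numbered 2, followed no sample (rho between 0.809 and 0.832), and TRPM2-AS siRNA replicate 3 had no such column. That 1 column was left out of the comparison because its sample could not be traced, and 4 control and 3 TRPM2-AS siRNA arrays were compared. This departs from the planned fit on 8 arrays. The fit on the authors' processed values of all 8 samples, planned as an alternative, and a fit with all 8 columns under their names, added after seeing the data, stand beside the main counts.

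Signals were corrected with the normal-exponential model of limma 3.58.1 in R 4.3.3, which took the background from the detection p-values and added an offset of 16, then were quantile normalized and put on the log2 scale. Probes with a detection p under 0.01 on at least 4 of the 7 arrays were kept, 13675 of 48798. That rule leaves out a gene seen on 3 TRPM2-AS siRNA arrays and 0 control arrays, while a gene seen on 4 control arrays alone passes. Of the shared probes, 28094 had 1 gene name in the platform annotation, 13 had several and 20691 had none, and 0 names needed an update through gene identifiers in the RefSeq table. For each gene the probe with the highest mean was used, which gave 9272 genes. TRPM2 and TRPM2-AS, both on chromosome 21, had 0 named probes.

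Groups were compared with limma's lmFit and eBayes (two-sided, Benjamini-Hochberg adjusted p under 0.05), and 27 gene lists with 519 entries were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the 12 highest and 12 lowest fold changes among genes that passed with the groups fully apart, and up to 4 members of each list with the smallest p. Exceptions to the direction of a list and genes detected in TRPM2-AS siRNA arrays alone were named after their values were seen. Some other untested list members stayed undetected in both groups, among them VLDLR, JDP2, BBC3, FAS, MDM2, FOSL2, FN1, ZEB2 and SPARC. Where a gene was not above background in any array of a group, the fold is a lower bound, the bright group's mean over the mean of, per array, the higher of the dimmest detected probe and the gene's own signal. The fit was tested on simulated data for this comparison, with 200 single genes and a list of 20 more changed among 9272. Of the 200, it called 29.9% of genes changed by 0.5, 80.6% by 1 and 100% by 2 on the log2 scale. Of its calls, 5.84% were genes simulated without change. Since 56.9% of genes changed in the real arrays and simulated genes varied independently, these rates do not describe the real comparison. The number of arrays limits the precision, and the median SE of a log2 fold change was 0.14.

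Alternatives covered the background correction and its offset, normalization by 1 median per array or cyclic loess, the detection filter, the probe per gene, the variance model, array weights, the authors' processed values, the replicate number as a block, each array left out in turn, the correlation in camera, camera on ranks, probes in place of genes and a test against a fold of 1.2. Added after seeing the data were all 8 columns, detection on at least 3 arrays, processed values with background correction, the block on processed values and 1 median over detected probes. A chip block was not run since no chip is named in the files used here. Figures were drawn with matplotlib 3.10.9.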

Results

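The series asked what depletion of TRPM2-AS does to gene expression in PC3 cells. Total RNA from 4 samples given control siRNA and 4 given TRPM2-AS siRNA was measured on Illumina bead arrays 48 hours after transfection, and 4 control and 3 TRPM2-AS siRNA arrays could be traced from raw signal to sample. Control arrays detected 13163 to 13972 probes and TRPM2-AS siRNA arrays 13832 to 14318. Log2 signals correlated across probes at 0.992 to 0.994 among control arrays, 0.990 to 0.994 among TRPM2-AS siRNA arrays and 0.963 to 0.970 between the groups; probes are not independent replicates. No probe was named for TRPM2-AS or TRPM2, so the depletion itself was not analysed here.

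The highest fitted fold change belonged to IL24, a cytokine of the interleukin 10 family, which rose 175-fold from a mean log2 intensity of 6.16 ± 0.30 (SD, n = 4) to 13.61 ± 0.24 (SD, n = 3; log2 fold change 7.45 ± 0.17 SE, limma adjusted p = 5.92e-10); 3 of 4 control arrays detected it. The inflammatory cytokines IL6 (59.1-fold), IL1B (42.0-fold) and CXCL8 (34.7-fold) followed. Further among the 12 highest by fitted fold were FABP4, a fatty acid carrier detected on 2 of 4 control arrays, with 20.8-fold, the secretory chaperone SCG5 with a log2 fold change of 4.32, the stress cytokine GDF15 with 16.1-fold and RGS4, a regulator of G-protein signalling detected on 1 of 4 control arrays, with 15.5-fold. KISS1 (15.3-fold), KRT34 (15.2-fold), the growth factor HBEGF (15.1-fold) and IL1RAPL1 (log2 fold change 3.70) completed them. With undetected control arrays set at the dimmest detected probe of the array, the folds were 169 for IL24, 19.6 for SCG5, 15.7 for FABP4 and 11.4 for RGS4.

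The receptor tyrosine kinase AXL had the largest fall among genes detected in both groups, 12.8-fold, from 11.59 ± 0.09 (SD, n = 4) to 7.92 ± 0.25 (SD, n = 3; log2 fold change -3.67 ± 0.13 SE, limma adjusted p = 1.16e-08). NHP2, a protein of small nucleolar and telomerase ribonucleoproteins, fell 9.35-fold, the kinase PRKCA 9.22-fold and the endoplasmic reticulum lectin MLEC 8.82-fold. The mitotic kinesin KIF20A fell 8.70-fold, the topoisomerase TOP2A 8.43-fold and ARL2 8.29-fold. KCNIP3 and the actin regulator ENAH were not above background on any TRPM2-AS siRNA array and fell at least 4.35-fold and at least 3.73-fold. PPIL1 (7.30-fold), TMED10 (7.18-fold) and LAMTOR2 (6.71-fold) also fell. In the authors' processed values of 4 against 4 samples the log2 fold changes were 6.17 for IL24 and -3.13 for AXL, and over all genes their slope on the values given here was 0.766.

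**Figure D1:**
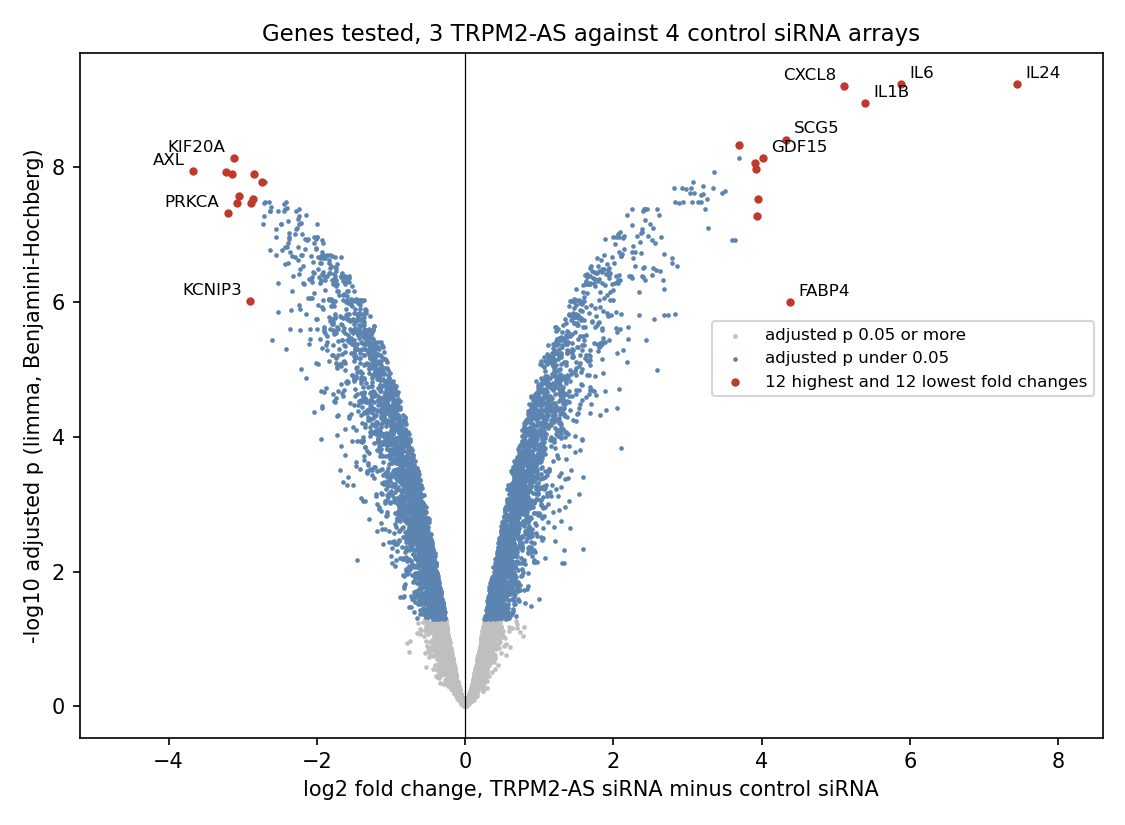
Each point is 1 of the 9272 genes, with the log2 fold change of TRPM2-AS siRNA over control siRNA on the horizontal axis and -log10 of the adjusted p from limma on the vertical axis. The 12 highest and 12 lowest fold changes are in red; IL24 lies farthest right at 7.45 and AXL farthest left at -3.67, with KCNIP3 and ENAH drawn at fitted values that are not bounds.

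Of 9272 genes, 5280 (56.9%) changed, 2541 higher and 2739 lower with TRPM2-AS siRNA (limma, adjusted p under the limit). At least 2-fold changes numbered 1629, with 732 genes higher and 897 lower; 124 genes rose and 111 fell at least 4-fold. The detection filter takes in genes seen on control arrays alone but not on TRPM2-AS siRNA arrays alone, and with no filter 2795 genes were higher and 2757 lower, 902 and 926 at least 2-fold. The groups were fully apart in 5310 genes (57.3%), against 5.71% by chance. The median log2 fold change of all genes was -0.01. Quantile normalization gives every array the same distribution, so a shift of all genes together could not have shown. The authors' processed values gave 5707 changed genes, 929 of them at least 2-fold. Of the 5280, 5138 also passed there in the same direction and 0 passed in the opposite direction. With the untraced column kept under its name as a TRPM2-AS siRNA array, 2450 genes changed, 922 at least 2-fold, and 40 of the 125 named genes, IL24, IL6 and GDF15 among them, no longer passed (IL24 log2 fold change 5.23, limma adjusted p = 0.0551, the highest among its alternatives, whose lowest was 6.88e-18).

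Inflammatory and antiviral genes rose together. All 9 tested members of the NF-kB and cytokine list rose, with a median log2 fold change of 2.82 (limma camera adjusted p = 1.86e-08); besides IL6, CXCL8 and IL1B these included TNFAIP3, a feedback inhibitor of NF-kB, with 7.05-fold. Members seen on 3 of 3 TRPM2-AS siRNA arrays and 0 of 4 control arrays were chosen after their values were seen. CCL20 was at least 10.6-fold, IL1A at least 3.55-fold and CXCL1 at least 2.58-fold higher. PTGS2 was seen in the same arrays with no fold to give. Of the other untested members, CXCL3, CXCL5, CCL2 and ICAM1 were detected on 0 arrays of either group. TNF was detected on 1 TRPM2-AS siRNA array and 0 control arrays. In the interferon response list 15 of 16 members rose and 0 fell (median 1.70, limma camera adjusted p = 2.19e-08), among them the antiviral RNA-binding genes IFIT2 (12.1-fold), IFIT1 (11.4-fold) and IFIT3 (7.39-fold) and the ISG15 ligase HERC5 (4.22-fold). IFI35 had a log2 fold change of -0.02. With an estimated correlation the limma camera adjusted p was 0.0193 for NF-kB and cytokine genes and 0.0306 for interferon response genes. OASL was at least 9.46-fold higher, the RNA sensor IFIH1 at least 2.69-fold, OAS2 at least 1.86-fold and IFI27 at least 1.33-fold, all 4 from background. OAS1 was seen on 2 and IFI44L on 1 of the TRPM2-AS siRNA arrays, and MX2, BST2 and PSMB9 on 0 arrays of either group.

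Mitotic genes fell. Of 30 genes of G2 and mitosis, 29 fell and 0 rose, with a median log2 fold change of -1.52 (limma camera adjusted p = 3.94e-13), or -1.48 with MKI67, not above background on any TRPM2-AS siRNA array, set at its bound of 1.95-fold. With an estimated correlation the list had a limma camera adjusted p of 0.0193. Besides KIF20A and TOP2A, the kinetochore motor CENPE fell 4.74-fold and the spindle protein NUSAP1 4.59-fold, and CENPA, at -0.16, did not pass. Of 26 S phase and replication genes, 13 fell and 2 rose (median -0.38), and the list did not pass (limma camera adjusted p = 0.101): UHRF1 fell 2.24-fold, TYMS 1.56-fold and POLE2 1.53-fold, while the clamp loader subunit RFC5 rose 2.81-fold. Among 12 cell cycle inhibitors and G1 cyclins, 4 rose and 3 fell (median 0.00, turning to -0.0228 with 1 median per array in place of quantile normalization; limma camera adjusted p = 0.542). CDKN1A, encoding the kinase inhibitor p21, rose 9.06-fold, CDKN2D 2.49-fold and CCND1 1.45-fold, and RBL2 fell 1.96-fold.

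**Figure D2:**
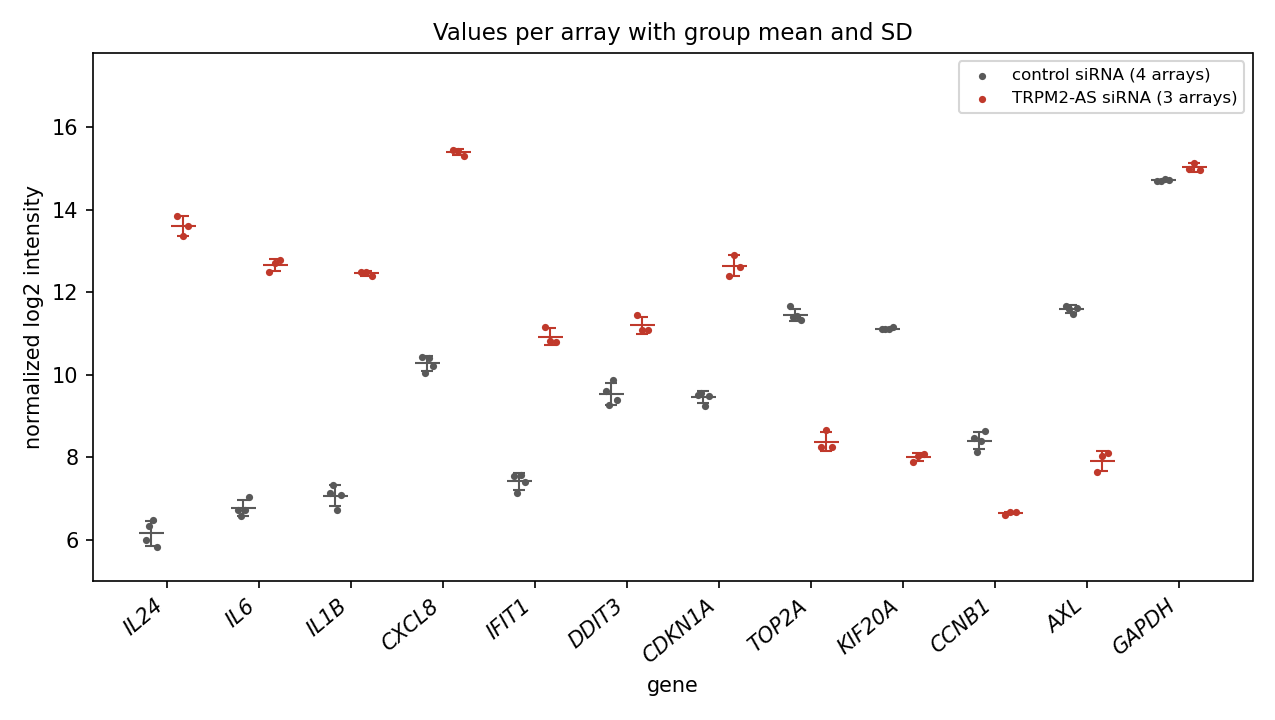
Normalized log2 intensity of 12 genes on each of the 4 control siRNA arrays (grey) and 3 TRPM2-AS siRNA arrays (red), with the group mean and SD as bars. IL24 lies near 6.16 in controls and 13.61 with TRPM2-AS siRNA, while TOP2A, KIF20A, CCNB1 and AXL lie lower with TRPM2-AS siRNA.

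Stress response genes rose. Of 23 ATF4 and CHOP targets, 19 rose and 0 fell (median 0.83, limma camera adjusted p = 4.15e-07), among them the mTORC1 inhibitor DDIT4 (5.30-fold), ATF3 (5.13-fold), DDIT3, which encodes CHOP (3.19-fold), and GADD45A (2.86-fold); SESN2 was at least 4.86-fold higher, from background. With an estimated correlation the ATF4 and CHOP list had a limma camera adjusted p of 0.0306. Chaperones of the endoplasmic reticulum and XBP1 or ATF6 targets went both ways, with 9 of 20 higher and 2 lower (median 0.21, limma camera adjusted p = 0.0765). HSPA5, the main chaperone of that compartment, rose 2.80-fold and SEC24D 2.23-fold. DNAJC3, detected on 2 of 4 control arrays, rose 3.70-fold as fitted and 3.09-fold with undetected arrays at the dimmest detected probe. Of 15 autophagy and lysosome genes, 10 rose and 0 fell (median 1.03, limma camera adjusted p = 0.000276), with GABARAPL1, which acts in autophagosome formation, at 5.78-fold, CTSL at 2.59-fold, the kinase ULK1 at 2.54-fold and WIPI1 at 2.51-fold. The autophagy median fell to 0.66, 0.49 and 0.52 without TRPM2-AS siRNA samples of replicate 1, 2 and 4 in turn (array columns 1, 3 and 4), and the list still passed. Among 13 cytosolic heat shock proteins, 4 rose and 2 fell (median 0.11, limma camera adjusted p = 0.313), HSPB1 being 1.86-fold higher and HSPA4 1.78-fold lower.

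Immediate early and matrix genes rose as well. Of 14 AP-1 and immediate early genes, 11 rose and 1 fell (median 1.06, limma camera adjusted p = 8.51e-05): JUNB rose 11.1-fold, the phosphatase DUSP1 8.53-fold and IER3 3.70-fold, FOS was at least 2.65-fold higher from background, and MYC fell by 0.75 on the log2 scale. In the TGF-beta, matrix and mesenchymal list 11 of 15 rose and 2 fell (median 0.94, limma camera adjusted p = 0.000276), with the urokinase receptor PLAUR at 10.2-fold, the metalloprotease MMP9 at 9.11-fold, THBS1 at 5.90-fold and the transcription factor SNAI2 at 2.32-fold; VIM, at -0.30, and TGFB2, at -0.84, fell. TGFBI, outside those 15, was at least 2.60-fold higher from background. Epithelial adhesion genes went both ways, 3 of 8 higher and 3 lower (median 0.10, limma camera adjusted p = 0.751): CLDN7 rose 1.74-fold, TJP1 1.73-fold and JUP 1.58-fold, and EPCAM fell 2.21-fold. CDH1 was seen on 3 of 3 TRPM2-AS siRNA and 0 of 4 control arrays, with no fold to give.

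Of 15 genes that promote apoptosis 9 rose and 3 fell (median 0.44, limma camera adjusted p = 0.129). PMAIP1, which encodes the BCL2 antagonist NOXA, rose 4.77-fold, the TRAIL receptors TNFRSF10A and TNFRSF10B 2.60-fold and 2.21-fold, and BAX fell 1.91-fold. CYCS was at least 4.63-fold and BMF at least 1.43-fold higher from background. The list passed with detection on at least 3 arrays (median 0.47), a filter that let CYCS and BMF in through TRPM2-AS siRNA arrays alone. A pass under that filter is therefore not separate support. Of the 10 listed genes that restrain apoptosis, 5 were tested, and of these 4 rose and 0 fell (median 0.62, limma camera adjusted p = 0.0319, and adjusted p = 0.129 with an estimated correlation). BIRC2 rose 2.91-fold and MCL1 2.29-fold. BCL2L2 rose 1.24-fold, a call lost with 1 median per array, no filter on dim probes, all 8 columns or some single arrays left out. The p53 target list had 4 of 10 genes higher and 1 lower (median 0.28, limma camera adjusted p = 0.0765); GDF15 and PHLDA3 (2.85-fold) rose, TP53I3 fell 2.00-fold, and TP53INP1 was at least 2.31-fold higher from background; this list also passed with detection on at least 3 arrays (median 0.28). TP53INP1 entered the p53 list there in the same way, through TRPM2-AS siRNA arrays alone. PC3 cells are known to lack functional p53. In the NRF2 and oxidative stress list 5 of 14 rose and 3 fell (median 0.03, limma camera adjusted p = 0.542): HMOX1 rose 7.62-fold and SOD2 4.19-fold, whereas GPX1 fell 2.29-fold and NQO1 2.23-fold. Metallothioneins split into 4 higher, led by MT1G with 5.19-fold, and 3 lower, with MT1F down 1.92-fold (median 0.57, limma camera adjusted p = 0.542).

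Among metabolic lists, 9 of 20 hypoxia and glycolysis genes rose and 2 fell (median 0.27, limma camera adjusted p = 0.0319, and adjusted p = 0.119 with an estimated correlation), with ANKRD37 at 3.38-fold, NDRG1 at 2.90-fold and ADM at 2.88-fold. Of 15 cholesterol synthesis and SREBP targets, 9 fell and 1 rose (median -0.41, limma camera adjusted p = 0.0765): the desaturase SCD fell 4.14-fold and MSMO1 3.57-fold, and HMGCS1 rose 2.48-fold. Of 21 cytosolic ribosomal protein genes 9 fell and 1 rose (median -0.26, limma camera adjusted p = 0.0271, and adjusted p = 0.111 with an estimated correlation), RPL6 by 2.46-fold, RPS6 by 2.26-fold and RPS19 by 2.22-fold, and their probes may also bind transcripts of related pseudogenes. The respiratory chain list had 7 of 21 higher and 3 lower (median 0.11, limma camera adjusted p = 0.417), with ATP5MC1 down 2.21-fold. The aminoacyl-tRNA synthetases had 5 of 18 higher and 2 lower (median 0.20, limma camera adjusted p = 0.417), GARS1 being 1.61-fold higher and YARS1 1.92-fold lower.

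Of the neighbours of TRPM2 on chromosome 21, 4 of 11 were higher and 2 lower (median 0.22, turning to -0.14 with no filter on dim probes; mean 0.04, limma camera adjusted p = 0.652); RRP1B fell 1.97-fold, PTTG1IP rose 1.55-fold and UBE2G2 fell 1.68-fold, a call lost with the mean of its probes (log2 fold change -0.14), as another of its probes rose by 0.47. Of 8 genes for TRP channels and calcium entry 5 rose and 1 fell (median 0.45, limma camera adjusted p = 0.0646). The calcium release channel ITPR1 rose 3.60-fold and TRPM4 2.17-fold, and ITPR3 fell 1.46-fold. TRPC1, outside those 8, was detected on 3 control arrays and 0 TRPM2-AS siRNA arrays. Among 5 luminal prostate genes that respond to androgen, PMEPA1 (5.25-fold), STEAP2 (3.61-fold) and SLC45A3 (1.51-fold) rose. HOXB13 and FKBP5, the latter by at least 2.84-fold, fell (list median 0.59, limma camera adjusted p = 0.417). KLK2, KLK3, KLK4, FOLH1, ACPP and TRPM8, also in that list, were detected on 0 arrays of either group. Of the fibroblast and blood cell markers 3 were detected widely enough to test: CD68 fell 2.77-fold, and CD14 (-0.28) and ACTA2 (-0.14) did not pass. Among 12 housekeeping genes GAPDH (1.24-fold) and B2M (1.38-fold) rose and GUSB (1.75-fold) and POLR2A (1.36-fold) fell (median 0.05, mean -0.04, limma camera adjusted p = 0.989). The GAPDH call was lost with 1 median per array, cyclic loess, no filter on dim probes, a looser detection p, the mean of its probes or all 8 columns. It was also lost without control column 1 or 3 or TRPM2-AS siRNA column 3.

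**Figure D3:**
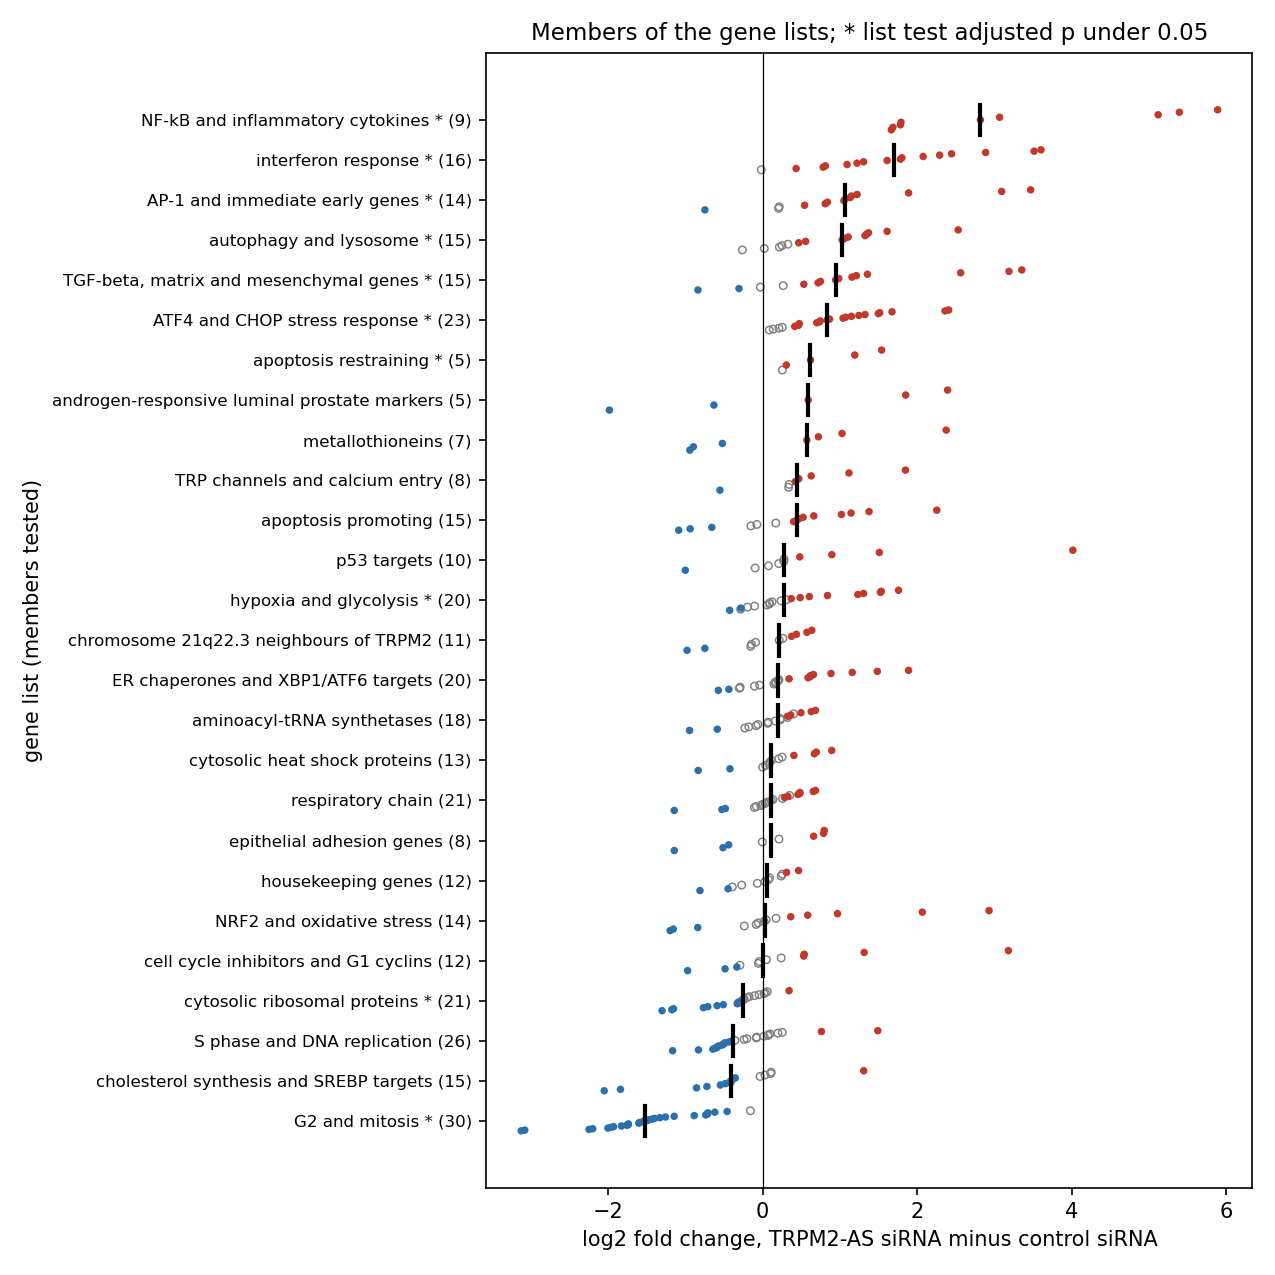
Log2 fold changes of the tested members of 26 gene lists (horizontal axis), ordered by their medians (black bars); filled points passed the test for single genes, red higher and blue lower, and open points did not. G2 and mitosis genes lie lowest, with a median of -1.52, and NF-kB and cytokine genes highest, at 2.82.

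In all, 10 of the 26 lists tested passed, and 7 of them also passed with an estimated correlation: G2 and mitosis, NF-kB and cytokines, interferon response, ATF4 and CHOP, AP-1 and immediate early genes, autophagy, and TGF-beta and matrix genes. Counts adjusted over the list alone equalled those over all genes in each of the 27 lists except the respiratory chain, with 6 in place of 7 higher. At the preset correlation, 4 of the 35 splits of the 7 arrays, the real one included, passed at least 10 lists; the other 3 kept the groups apart in part.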

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

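The fits with 1 shift per array and with single arrays left out were planned; their use as tests here, the splits of the arrays, and the tests on the untraced column, on other cell types and on the siRNA duplex were chosen after the results were seen.

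More than 1 in 2 tested genes changed with TRPM2-AS siRNA, including IL24, IL6 and the mitotic genes. Of the 35 splits of the 7 arrays into 4 and 3, 1 gave as many genes, the real one with 5280. The highest of the others gave 0 (5727 against 3111 at an unadjusted p under 0.05, limma). The same held for changes of at least 2-fold (1 split, 1629 genes against 0). If the arrays are independent, random labels of these 7 would put the real split first in 1 of 35 cases, so chance is then argued against but not excluded. The labels do not say whether replicates came from separate cultures. The counts of 0 add nothing, since the treatment difference lies within the groups of the other splits. Quantile normalization is argued against as the source, since 4877 genes changed with 1 shift per array in its place. An effect of the TRPM2-AS siRNA, which the groups name, stays open. It cannot be told apart here from a difference between cultures or chips that follows the groups, since neither is named.

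The column named as a TRPM2-AS siRNA array but matching no sample lay near the control arrays. A diluted response, with all genes in proportion, is argued against by the NF-kB and cytokine genes, whose median was -0.21 from the control mean on the log2 scale. A response in part of the genes stays open: the slope along the TRPM2-AS siRNA response was 0.122, against at most 0.00621 for control arrays, the interferon median was 0.50, and over 6 splits of the control arrays a mean of 107 (97 to 116) of 226 (205 to 254) genes raised at least 2-fold were also raised by TRPM2-AS siRNA, while ATF4 and CHOP targets (-0.60) and AP-1 genes (-0.36), which rose with TRPM2-AS siRNA, lay below every control array. A control array prepared with the other 4 is argued against by the SD over genes of its difference from the control mean, 0.464 against 0.199 to 0.253 for control arrays. Cells given another siRNA or treatment cannot be told apart from such a partial response, since 0 samples carry such a label.

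Interferon and NF-kB genes such as IFIT1, IFIT2, IL6 and CXCL8 rose together. A sizeable share of blood or fibroblast cells is argued against. Of their 12 markers with a named probe, 0 rose or were newly detected on a TRPM2-AS siRNA array. CD68, CD14 and ACTA2 were also detected in controls, and CD68 fell. Other epithelial cells have no markers in that list and a small admixture could go unseen, so neither was excluded. A single outlying array is argued against, since the interferon median was at least 1.59 with any 1 TRPM2-AS siRNA array left out. Innate sensing of the siRNA duplex cannot be told apart from loss of TRPM2-AS, since the labels name 1 TRPM2-AS siRNA and a second sequence would be needed. Direct effects of that siRNA on transcripts other than TRPM2-AS were not tested either, since its sequence is not given in the sources used here.

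With the preset correlation 4 of the 35 splits passed as many lists, up to 13 in the highest other, against 10 in the real split, so chance was not excluded for that count. Those other 3 splits held much of the treatment contrast: that highest split set 3 control arrays against 1 control and 3 TRPM2-AS siRNA arrays, and the others, with up to 11 lists, kept 2 of the 3 TRPM2-AS siRNA arrays together. Splits with 1 TRPM2-AS siRNA array among the 3 passed at most 3 lists. With an estimated correlation the real split passed 7 lists and the highest other 0 (limma camera), which decides nothing: the treatment difference lies within the groups of the other splits, and those with 13, 11 and 10 lists at the preset correlation passed 0 too.

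A single array stood apart from the other 3 of its group, by its gap over the group's range, in 17 of the 250 groups tested for 125 named genes, and chance alone gives about 1 in 20. Among control arrays the ratio was 0.959 for IL1RAPL1 and CD14, 0.957 for KARS1, 0.916 for UHRF1, 0.906 for UQCRC1, 0.881 for IFIT3, 0.862 for KIF20A, 0.843 for NHP2 and 0.841 for B2M. Among the 4 TRPM2-AS siRNA samples of the authors' processed values it was 0.930 for ITPR3, 0.920 for TNFRSF10B, 0.858 for UHRF1 and SNAI2, 0.853 for HMOX1 and BAG3, 0.844 for EPCAM and 0.832 for RGS4.

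In the untraced column 4 gene lists had medians above every control array and over 0.2 above the control mean on the log2 scale: interferon response at 0.50, hypoxia and glycolysis at 0.29, respiratory chain at 0.23 and TRP channels and calcium entry at 0.22. Another 4 had medians below every control array and over 0.2 below the control mean: metallothioneins at -0.67, ATF4 and CHOP targets at -0.60, AP-1 and immediate early genes at -0.36 and NF-kB and cytokine genes at -0.21.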

How the results depend on the processing

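Of 3099 values of the 125 named genes under alternatives, 3039 kept their direction and side of the threshold, 58 lost the threshold, 2 gained it and 0 turned. Most of these genes were named for a large fold change or small p in the main fit of the same arrays. That choice favours unchanged calls, so the count does not show how far other genes depend on the processing. Outside the fit with all 8 columns, 4 genes changed side: GAPDH, BCL2L2, UBE2G2 and CD14. CD14 passed as lower with array weights (log2 fold change -0.31) and without TRPM2-AS siRNA column 3 (-0.38), and the other genes lost the threshold. Alternatives with all 8 columns, detection on at least 3 arrays, normexp on processed values, the replicate block on processed values, and 1 median over detected probes were chosen after seeing the data. The target gene was not run, having no named probe, nor was a chip block. The cause of the differences below was not tested, except where fewer or other genes or another threshold are the change itself, or where a value is given.

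Changed genes numbered 2450 (1217 higher, 1233 lower) with all 8 columns and 3373 (1571 and 1802) against a fold of 1.2. Genes changed at least 2-fold numbered 945 (437 and 508) without background correction, 929 (421 and 508) in the processed values with or without the replicate block, and 922 (458 and 464) with all 8 columns. Leaving out background correction alone thus took the 7 arrays from 1629 to 945, close to the 929 of the processed values. Processed values with normexp gave 1308 (589 and 719), but there the correction was made on already normalized values and without detection p-values. Background correction accounts for at least part of the difference of 929 from 1629, and its absence is enough for a count near 929. Leaving out each array gave 4716 to 5072 changed and 1519 to 1642 2-fold genes. Replicate numbers paired the samples at most in part. Deviations of same-numbered samples correlated at 0.392 for replicate 1, -0.0723 for 2, 0.0930 for 3 and 0.229 for 4. Only 4 of 8 samples, those of replicates 1 and 4, correlated best with their own number. The replicate block on the 7 arrays gave 5352 changed genes against 5280, and in processed values 6011 against 5707.

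The median of cell cycle inhibitors turned to -0.0228 with 1 median per array, -0.00810 with the replicate block, -0.00928 in processed values with or without that block, -0.0171 with normexp on them and -0.0473 with all 8 columns, and ran from -0.0197 to 0.117 with an array left out. The TRPM2 neighbours turned to -0.144 with no filter and -0.0906 with detection p under 0.05 on 1 array, and housekeeping genes ran from -0.0270 to 0.105 with an array left out. None of these lists passed. Nor did others whose medians moved by over 1.5 times with an array left out: NRF2 (0.0169 to 0.0795), aminoacyl-tRNA synthetases (0.124 to 0.227), epithelial adhesion (0.0643 to 0.148), TRPM2 neighbours (0.120 to 0.241) and heat shock proteins (0.0928 to 0.174).

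Other lists crossed the threshold. Hypoxia was lost with cyclic loess (0.28). With no filter ER chaperones (0.20), S phase (-0.24), apoptosis promoting (0.44), cholesterol (-0.38) and p53 (0.28) passed and apoptosis restraining (0.34) was lost. With detection p under 0.05 on 1 array apoptosis promoting (0.47) and cholesterol (-0.39) passed and restraining (0.32) was lost. By largest variance p53 (0.38) and TRP (0.59) passed, and with the replicate block TRP (0.50). Cholesterol passed in processed values (-0.37), and with the block there again (-0.37) together with ER chaperones (0.23). With all 8 columns S phase (-0.31) and p53 (0.21) passed and restraining (0.47) was lost. With detection on 3 arrays apoptosis promoting (0.47) and p53 (0.28) passed, each with members let in through TRPM2-AS siRNA arrays alone. With an estimated correlation restraining (0.62), hypoxia (0.27) and ribosomal genes (-0.26) were lost; their adjusted p (limma) ran over alternatives from 0.0254 to 0.194, 0.0120 to 0.119 and 0.00223 to 0.111. TRP ran from 0.34 to 0.51 with an array left out and passed without 1 TRPM2-AS siRNA array. Dim signal limits genes near background: detection on 3 arrays added 357 genes, 213 higher and 49 lower.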

Other observations

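The tests and the genes named in these paragraphs were chosen after seeing the data. Among 145 families of genes that share a symbol stem and have at least 8 tested members, 3 passed limma's camera at the preset correlation and 0 with an estimated one. The kinesin motors (KIF) had 15 of 21 members lower and 4 higher (median -1.05, limma camera adjusted p = 0.0453, and adjusted p = 0.852 with an estimated correlation). Among those that changed were the mitotic motors KIF4A (log2 fold change -1.52) and KIF2C (-1.37), and KIF3B (-1.92), KIF5B (-1.06) and KIF1C (0.77), each known for transport of vesicles or organelles. Symbols starting with IL had 12 of 27 members higher and 2 lower (median 0.29, limma camera adjusted p = 0.0346, and adjusted p = 0.852 with an estimated correlation): the receptor IL13RA2 (2.80), the cytokine IL32 (2.64) and the IL6 co-receptor IL6ST (2.15) rose and IL18BP (-0.94) fell. Large-subunit ribosomal genes and their pseudogenes (RPL) had 23 of 52 lower and 3 higher (median -0.28, limma camera adjusted p = 0.0346, and adjusted p = 0.852 with an estimated correlation), RPL14 falling by 2.19 and RPL13A by 1.74.

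Probes of 1 gene could disagree in direction: of 985 genes with at least 2 changed probes, 42 (4.26%) had probes that changed in opposite directions, and 0 of these did so by at least 2-fold both ways. STARD7 had probes at -0.99 and 1.02.

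In the untraced column IL24 had a log2 intensity of 4.79, against a mean of 6.20 in control and 13.65 in TRPM2-AS siRNA arrays when all 8 columns were normalized together, and 23 of the 24 genes with the highest and lowest fold changes lay nearer the control mean; FABP4, at 8.40 against 5.81 and 10.21, was the exception. Along the TRPM2-AS siRNA response over changed genes its slope was 0.122 (0.120 to 0.125 over control splits), with control arrays at most 0.00621. A hypothesis that the column shares part of the response was tested with separate control arrays for the column and for the TRPM2-AS siRNA arrays: over the 6 splits of the control arrays a mean of 226 genes (205 to 254) were at least 2-fold higher in the column, and a mean of 107 (97 to 116) were so in the TRPM2-AS siRNA arrays too, against a mean of 18 for independent lists (Fisher's exact test over genes, which are not independent, largest p 6.86e-52). At least 2-fold lower were a mean of 208 (202 to 219), with a mean of 39 (35 to 43) shared, against 20.5 (largest Fisher's exact p 0.000665). The number for independent lists takes every gene as equally likely to pass, and genes were not matched by intensity or variance. Chance overlap of the raised genes is argued against only in that setting. A shared transfection or culture response may be involved, which 1 untraced column cannot settle.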
